A study of Arabidopsis thaliana with 36 samples.

How the data were processed

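Total RNA depleted of ribosomal RNA was sequenced on a NovaSeq 6000 from 36 libraries of Arabidopsis thaliana seedlings, in 12 groups of 3 libraries with reads of 150 bp. The groups combine 6 genotypes with darkness or red light, and each library was assigned to its group by the labels. The labels do not state that the 3 libraries of a group came from separately grown seedlings. The authors' p-values, and those built on their standard errors, therefore measure only the spread between these libraries. Fisher's exact and exact binomial tests count genes, regions or transcripts, and their p-values measure no spread between libraries. The files analysed here hold results of the authors' comparisons of whole groups and no value for a single library, so the depth of each library is unknown.

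The submitters' processing notes name FastQC, STAR, HTSeq and DESeq2 and the genome build TAIR10, and the series design text names ASpli 2.0. Versions of the other tools are not given in the sources used here. In the 4 expression tables the authors give, per transcript, the DESeq2 base mean, a normalised signal averaged over the libraries of a comparison. The deposited fold changes and their standard errors (SE) are on the log2 scale, beside the authors' Wald statistic, a score for each transcript. Each deposited transcript carries a p-value and an adjusted p-value, and the tables hold only called transcripts, with an adjusted p-value of at most 0.05 and an absolute log2 fold change of at least 0.58. From ranks and adjusted p-values, at least 28332 transcripts were tested by the authors in each comparison.

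The 12 splicing tables hold regions called by the authors with ASpli. A bin is a stretch of exon or intron whose coverage is compared with the coverage of its gene, and per the file headers it has a log2 fold change and an FDR. Junction regions (anchor and locale) have an FDR and a change. Per the file headers it is a change in inclusion for anchor regions and a change in participation of a junction for locale regions. Below, inclusion change stands for either kind. Both are differences of fractions given without a sign, so junction regions give no direction. Per the file headers, anchor regions also carry a likelihood ratio score. The headers name a bin fold change of 1.5, junction FDR of 0.01 and junction change of 0.3, and a bin FDR of 0.05 in the 4 tables of WT and swap1 but 0.03 in the 8 tables with the triple mutant. Some called bins lie below the named fold (10 in WT between lights and 188 in the triple mutant against WT in red light). The 16 deposited gene ontology (GO) tables give, per the file headers, the number of genes, a relative enrichment ratio and an adjusted p-value per term, with no background named, and the authors chose the terms on these samples.

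The headers do not make clear which group is the numerator of a fold change, so the direction was settled from the values. This departs from the rule fixed beforehand, which took the column names, then SWAP1 in the tables of swap1 and known light-regulated genes in the tables of light. Known light-regulated genes gave red light over dark, but taken literally the SWAP1 rule gives the opposite of the direction used here: the only SWAP1 transcript called between the genotypes, AT4G31200.3 in red light, is higher in swap1 under the direction used and lower under the other. The rule was set aside because it rests on 1 minor transcript of a gene whose mutant allele is not known here to lower its transcript level, and the values of all 4 tables together contradict it. The 4 expression comparisons form a closed loop, and over 535 transcripts called in all 4 the loop closed to a median of 0.00302 log2 units for 1 choice of signs and 0.628 for the next best. Group means solved from base mean and fold change differed between tables by a median of 0.0567 to 0.149 log2 units under that choice and by at least 0.881 under every other. The genotype tables were therefore turned, and all values here are swap1 over WT and red light over dark. Bin fold changes closed over 49 bins to 1.00e-03 as second over first group, and bins specific to an isoform moved in the direction of that isoform in 75.5% to 81.9% of cases. Of 9997 bins with a locus in the TAIR10 annotation, 99.4% lay inside that locus, and 97.8% of 8629 intron bins equalled an annotated intron.

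No test over libraries was possible, and the authors' calls were counted. For transcripts called in both comparisons of a pair with no shared library, the difference of the 2 log2 fold changes was divided by the root of the summed squared deposited SE, with a two-sided normal p-value adjusted by Benjamini-Hochberg (BH) and a threshold of 0.05. This test was checked on simulated data with the deposited SE. The simulated noise was normal with exactly these SE and was not filtered by the calling thresholds. The check therefore cannot show how well the deposited SE measure the real spread. Simulated log2 differences of 0.5, 1.0, 1.5 and 2.0 were recovered in 40.0%, 68.0%, 90.0% and 84.0% of transcripts for the light response and in 26.0%, 46.0%, 78.0% and 90.0% for the swap1 effect, and 2.76% and 6.25% of simulated calls were false. The test does not cover transcripts called in only 1 of the tables. The difference can also be reached through either pair of tables, and the SE of both routes had a median ratio of 0.999 over 535 transcripts.

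Genes of 14 fixed lists with 232 members were counted as called or not and compared with the 27444 protein-coding nuclear genes of the annotation by two-sided Fisher's exact tests, BH adjusted over 224 tests of lists and tables. That background is too wide, because the tables hold only called genes. A count adjusted over the list alone cannot be given, since it needs the p-values of uncalled members. List values are those of the called transcript of highest base mean per locus. Overlaps of gene sets used one-sided Fisher's exact tests with the same background. Shares of introns with higher retention have exact Clopper-Pearson 95% intervals and were compared between comparisons by Fisher's exact tests, BH adjusted over 6 tests. These intervals count regions, which are not independent of each other, and not libraries. Overlaps of comparisons with a shared control group were set beside 100 simulated draws with a correlation of 0.5 from that group. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used.

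The lists, the rule for named genes, most tests and most alternative settings were fixed before the data were examined. Tests on small nucleolar RNAs, pseudogenes and other transcript groups were chosen after seeing the data. So were those on the WT red-light libraries and on shared regions of the doubles. Named genes are the 5 highest and 5 lowest log2 fold changes per expression table at a base mean of at least 50, up to 4 called members of each list by absolute log2 fold change, and SWAP1, SFPS, RRC1, PHYB, PIF1, PIF3, PIF4, PIF5, HY5 and COP1 where called. Named regions are the 5 of lowest FDR with an inclusion change of at least 0.2 in comparisons with WT or of swap1 between lights, the 3 of lowest FDR in comparisons of a double with the triple mutant, and up to 4 of largest change in loci of 6 lists. Inclusion changes and bin log2 fold changes are on different scales, so these 4 were taken as 2 by each. The 5 GO terms of lowest adjusted p-value with at least 10 genes were kept per table. Alternatives were stricter thresholds, larger minimum changes, a base mean of at least 50, counts by locus, overlap by locus or by 1 base, 1 region per locus, and called genes as the background of overlaps between expression comparisons. A bin FDR of 0.03 in every table, expression counted by locus, called genes as the background of the lists, and genes with introns as the background of the overlap of expression with splicing were added after seeing the data.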

Results

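RNA was measured in 36 libraries from seedlings of 6 Arabidopsis genotypes, 3 libraries in each of 12 groups. The genotypes were the wild type (WT), the single mutant swap1, the double mutants swap1sfps, swap1rrc1 and sfpsrrc1, and the triple mutant swap1sfpsrrc1, which lack function of 1 or more of 3 genes for splicing factors. Seedlings grew in darkness to an age of 4 days and then stayed dark or received red light at 7 µmol per square metre per second for 3 h. Expression was compared in WT and swap1, and splicing in all 6 genotypes. The comparisons ask how light changes transcripts and splicing, how the loss of SWAP1 changes both, and what each of the 3 factors adds when the others are lost. Depth per library is unknown, and each fold change below is the authors' over groups of 3 libraries, with a log2 fold change as red light over dark or as mutant over WT.

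The SWAP1 gene itself (AT4G31200, chromosome 4, 15161600 to 15164936) changed along its length in each comparison of a group with swap1 and a group without it. In the authors' deposited table for swap1 against WT, exon 4 of 5 (15161965 to 15162993) changed by -0.92 log2 units in the dark (FDR 5.86e-22) and -1.51 in red light (FDR 2.94e-55). Exon 3 (15163108 to 15163379) changed by -1.08 and -1.47 in the authors' deposited table, while intron 1 (15164618 to 15164831) rose by 0.86 and 1.70. Against WT, the triple mutant had exon 4 at -0.87 in the dark and -1.52 in red light and intron 1 at 0.83 and 1.82 in the authors' deposited table. Against sfpsrrc1, which keeps SWAP1, the triple mutant had exon 4 at -0.88 and -1.37 and exon 3 at -0.93 and -1.55 in the authors' deposited table. No SWAP1 bin was called between light conditions, and 1 was called where both groups carried swap1, exon 3 at 0.93 (FDR 0.00105) in the triple mutant against swap1rrc1 in the dark in the authors' deposited table. Of the SWAP1 transcripts, AT4G31200.3 was called at -0.86 (SE 0.27) by light in WT and at 0.92 (SE 0.28) in swap1 in red light in the authors' deposited table.

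**Figure D1:**
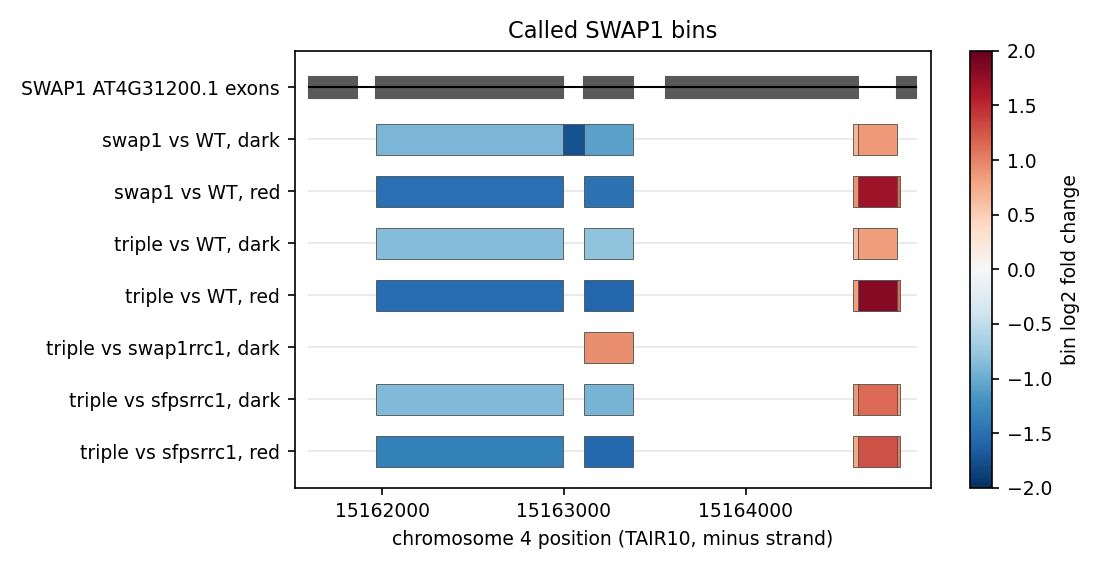
Called bins of SWAP1 along chromosome 4 (bases, horizontal axis), 1 comparison per line, coloured by bin log2 fold change, with the exons of AT4G31200.1 at the top. Exons 3 and 4 are lower and intron 1 is higher in each comparison of a group with swap1 to a group without it, with exon 4 at -1.51 and intron 1 at 1.70 in swap1 against WT in red light.

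The RRC1 gene (AT5G25060, chromosome 5, 8633114 to 8640217) changed near its end when rrc1 was added to swap1sfps. Exon 16 of 17 (8634670 to 8634833) changed by -0.70 in the dark (FDR 1.84e-36) and -0.84 in red light (FDR 8.06e-20) in the authors' deposited table, and intron 15 beside it (8634834 to 8635302) rose by 0.64 and 0.86. Intron 16 (8634509 to 8634669) was higher in the triple mutant than in swap1rrc1 (0.82 dark, 1.18 red) and than in sfpsrrc1 (0.70 dark, 0.81 red) in the authors' deposited table, although both doubles carry rrc1. RRC1 transcript was 0.87 (SE 0.06) higher in swap1 than in WT in the dark in the authors' deposited table, and fell by 0.68 (SE 0.12) with light in swap1. SFPS was called in none of the 4 expression or 12 splicing tables.

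Red light raised the genes of light harvesting, chlorophyll synthesis and flavonoid synthesis in WT and lowered those of auxin response and elongation growth. All 20 genes of the light-harvesting antenna were higher (BH p = 3.84e-12), with LHCA1 at 5.43 (SE 0.19) and LHCB2.2 at 4.94 (SE 0.11) in the authors' deposited table. Of 17 chlorophyll genes 12 rose and 2 fell (BH p = 3.71e-06): in the authors' deposited table GUN5 (magnesium chelatase) was at 2.63 and HEMA1 (glutamyl-tRNA reductase) at 2.33, while PORA and PORB, the protochlorophyllide reductases of dark-grown seedlings, were at -4.78 and -2.50. Of 25 auxin and elongation genes 18 fell and 0 rose (BH p = 2.44e-06), with PIL1 at -4.68, XTH15 at -4.01, ATHB2 at -3.23 and SAUR22 at -2.47 in the authors' deposited table. Of 18 flavonoid genes 13 rose and 0 fell (BH p = 6.34e-05), with LDOX at 5.08, TT8 at 4.16 and DFR at 3.91 in the authors' deposited table. In all, 3760 transcripts were higher in red light and 2467 lower.

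The regulators of the light response also changed in WT. Of 13 negative regulators of photomorphogenesis 8 rose and 1 fell (BH p = 0.00218), with PIF7 at 5.12, PIF4 at 3.01, SPA1 at 2.42, COP1 at 0.65 and PIF3 at -0.78 in the authors' deposited table. Of 20 photoreceptor and phytochrome signalling genes 5 rose and 6 fell (BH p = 0.00566): BBX25 was at 4.75, BBX24 at 2.32, HY5 at 1.19, PAR1 at -2.46 and FHL at -2.35 in the authors' deposited table. Clock genes changed in 16 of 24 cases, 13 higher and 3 lower (BH p = 2.92e-05), with LNK1 at 2.35, ELF4 at 2.33 and LHY at -2.42 in the authors' deposited table. Of 14 genes of the abscisic acid (ABA) response 9 rose (BH p = 0.00402), with COR15A at 10.48 (SE 1.66) and RD29A at 4.99 (SE 0.54) in the authors' deposited table. Of 10 heat shock genes 7 rose and 1 fell (BH p = 0.00124), with HSP70-4 at 2.62 and HSP22 at -2.21 in the authors' deposited table. The largest single changes were AT2G15020 (11.24), BBX16 (11.20), scpl10 (11.01), AT2G40435 (10.99) and AT5G24080 (10.86) upward and COPT3 (-10.20), bbx23 (-7.22), AT5G44255 (-6.99), AT1G72290 (-6.82) and GRF7 (-6.33) downward in the authors' deposited table. Their SE ran from 0.46 (scpl10) to 1.52 (AT5G24080), so these sizes are imprecise. The remaining lists did not pass: SR proteins (1 of 20 called, Fisher's exact test, BH p = 0.341), other splicing factors (3 of 28, 0.582), the mutated genes (1 of 3, 0.937), the embryo tissue markers of seed storage (3 of 12, all higher, 1.00) and the root hair markers (1 of 8, 1.00). The GO terms of lowest adjusted p-value in the authors' deposited table included photosynthesis (69 genes, 4.75e-19), response to light stimulus (101 genes, 2.15e-14) and circadian rhythm (53 genes, 3.11e-08). At an absolute log2 fold change of at least 1, the count was 3525 transcripts. Against only the genes called in some expression table, a background chosen after seeing the data, the antenna list alone among these 9 stayed past the threshold (Fisher's exact test, BH p = 5.92e-04).

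The same gene groups changed with light in swap1, and many changed more than in WT. In swap1 4364 transcripts rose and 3232 fell. Of 4679 transcripts called by light in both genotypes, 97.8% had the same direction, and 1233 differed in size or direction at a BH p below the threshold: 872 changed more in swap1, 258 less and 103 in the opposite direction. All 20 antenna genes rose (BH p = 7.61e-11), 12 of them more in swap1 and 0 less, such as LHCB2.2 at 5.50 against 4.94 in WT in the authors' deposited table (BH p of the difference 9.97e-04). The near-identical LHCB1 copies gave the largest antenna differences, LHCB1.4 at 12.18 against 6.96 and LHCB1.1 at 10.21 against 6.25 in the authors' deposited table. Reads may be shared between these copies, which was not checked and would make their separate values uncertain. Chlorophyll genes again had 12 higher and 2 lower (BH p = 2.36e-05), and 12 of the 13 measured in both differed, 10 of them larger in swap1, such as CRD1 at 2.86 against 2.12 in the authors' deposited table, while PORB fell less (-1.09 against -2.50). Auxin and elongation genes had 19 of 25 lower (BH p = 3.71e-06), 11 with a larger and 1 with a smaller fall, such as SAUR23 at -3.55 against -2.43 in the authors' deposited table. Flavonoid genes had 15 of 18 higher (BH p = 8.94e-06), 7 of 13 with a larger rise, such as 4CL3 at 3.52 (SE 0.42) against 1.09 (SE 0.45) in the authors' deposited table.

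**Figure D2:**
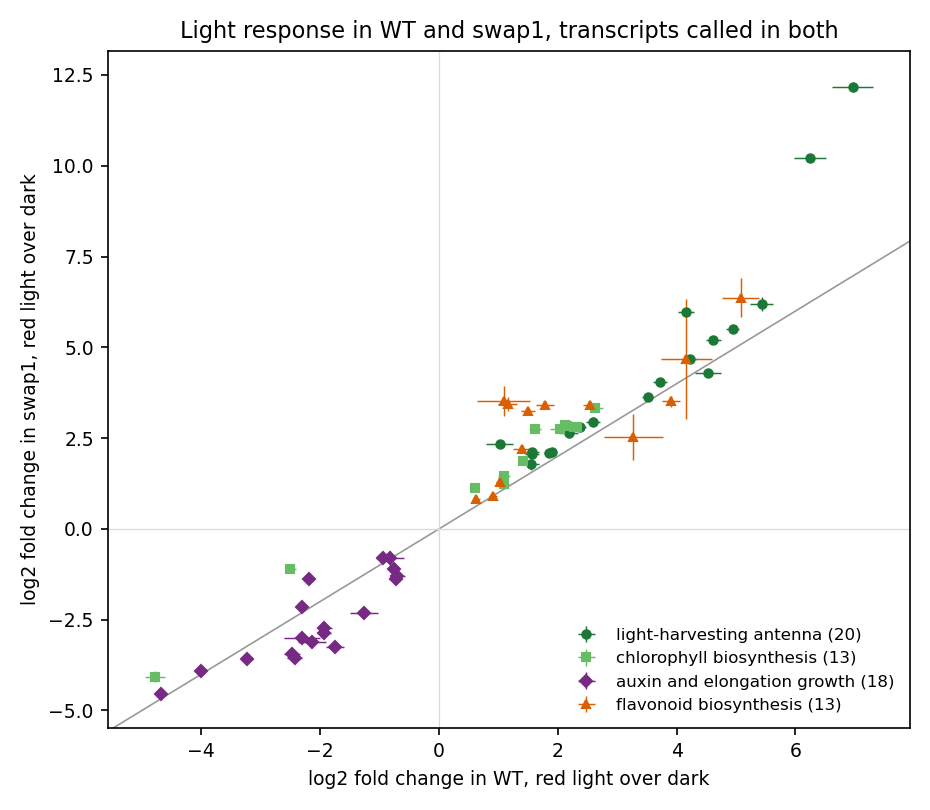
Log2 fold change of red light over dark in WT (horizontal axis) and in swap1 (vertical axis) for genes of 4 lists called in both, with the deposited SE as error bars and the line of equal change. Antenna genes lie on or above the line, up to 12.18 in swap1 for LHCB1.4, except LHCB1.5 (4.29 against 4.53).

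Other lists moved both ways between the genotypes. Negative regulators had 8 of 13 higher in swap1 (BH p = 0.0322), with a smaller rise of PIF4 (1.93 against 3.01) and a larger rise of SPA1 (3.02 against 2.42) in the authors' deposited table. Photoreceptor and signalling genes had 5 higher and 7 lower (BH p = 0.00631), with larger rises of HYH (3.10 against 1.49) and BBX25 (5.66 against 4.75) in the authors' deposited table, and PHYB at -0.74 in swap1. Clock genes had 10 higher and 7 lower (BH p = 5.07e-05), with ELF4 at 2.18, LNK1 at 1.80, BOA at -2.23 and JMJD5 at -3.70 in the authors' deposited table. ABA genes had 8 higher and 1 lower (BH p = 0.0136), 3 of 8 with a smaller rise in swap1, such as RD29A at 3.37 against 4.99 in the authors' deposited table. Heat shock genes had 7 higher and 1 lower (BH p = 0.00350), with HSP21 at 3.68 against 1.15 in the authors' deposited table. The largest changes in swap1 were scpl10 (13.66), THI2.2 (11.89), AT2G40435 (11.31) and AT2G15020 (11.12) upward, beside LHCB1.4, and CYP78A10 (-9.32), AT1G72290 (-9.16), AT5G44255 (-8.77), bbx23 (-8.17) and AT5G57760 (-6.93) downward in the authors' deposited table. Their SE reached 1.22 (AT1G72290). SR proteins (2 of 20 called), other splicing factors (9 of 28), mutated genes (1 of 3), seed storage (2 of 12) and root hair markers (1 of 8) did not pass (Fisher's exact test, lowest BH p = 0.506). Photosynthesis led the GO terms of the authors' deposited table (69 genes, 6.96e-15). At an absolute log2 fold change of at least 1, 4299 transcripts were counted. Of the 1233 transcripts that differed between genotypes, 799 did so at a BH p below 0.01 and 353 by at least 1. Against only called genes the antenna list alone among these 9 passed (Fisher's exact test, BH p = 0.0118).

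In the dark, PR1, a marker of salicylic acid defence, was much lower in swap1 than in WT, and some genes of the antenna, chlorophyll and flavonoid lists were lower. No list of this comparison stayed past the threshold against only called genes (Fisher's exact test, lowest BH p = 0.207). PR1 was at -5.47 (SE 0.13) in swap1 over WT in the authors' deposited table. Of 20 antenna genes 9 were lower and 0 higher (BH p = 0.00355), with LHCB1.4 at -4.68, LHCB1.1 at -3.73, LHCB1.2 at -1.84 and LHCB1.3 at -1.33 in the authors' deposited table, values of near-identical copies. Of 17 chlorophyll genes 6 were lower and 1 higher (BH p = 0.0218), with DVR at -1.49, GUN5 at -0.84 and CRD1 at -0.79 in the authors' deposited table. Of 18 flavonoid genes 9 were lower and 1 higher (BH p = 3.21e-04), with MYB11 at -3.18, FLS1 at -2.77 and CHS (chalcone synthase) at -2.39 in the authors' deposited table. Clock genes had 7 higher and 4 lower (BH p = 0.00102), with LUX at 1.19, CCA1 at -1.29, LHY at -1.27 and RVE8 at -1.12 in the authors' deposited table. ABA genes had 3 higher and 3 lower (BH p = 0.0322), with RD29A at 1.67 and KIN2 at -1.33 in the authors' deposited table.

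Single genes of lists that did not pass also changed in swap1 in the dark. The U2AF65A transcript AT4G36690.2 was at -1.87 and SKIP at 1.28 in the authors' deposited table, with RS31, an SR protein, at 0.82. HYH was at -1.54, BBX25 at -1.27, HFR1 at 0.69, CRY2 at 0.66 and PIF4 at 1.25 in the authors' deposited table. Beside PR1 and LHCB1.4, the lowest were CYP71A12 (-4.44), AT4G04750 (-4.32) and GASA5 (-4.19), and the highest were ATCG01200 (5.50), AT5G27845 (4.97), AT3G44215 (4.74), AT1G36630 (4.58) and AT1G24570 (4.22) in the authors' deposited table. In total 1779 transcripts were higher and 2154 lower. Lists that did not pass were photoreceptors (4 of 20 called), negative regulators (1 of 13), auxin (3 of 25), SR proteins (1 of 20), other splicing factors (2 of 28), mutated genes (1 of 3), heat shock (3 of 10), seed storage (4 of 12, all lower) and root hair markers (2 of 8, both higher), with a lowest BH p of 0.229. GO terms with the lowest adjusted p-values in the authors' deposited table were photosynthesis (30 genes, 0.00598), lignin catabolic process (10 genes, 0.0233) and response to cold (52 genes, 0.0494). The count was 1969 transcripts at an absolute log2 fold change of at least 1.

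In red light, PR1 was again much lower in swap1, and 6 of 12 seed storage genes were lower. Against only called genes the seed storage list did not pass (Fisher's exact test, BH p = 0.309), whereas the antenna list, with few of its genes called, did. All 20 antenna genes enter that background because light called them, so their shortage here is partly set by the choice of background. PR1 was at -5.47 (SE 0.14) in the authors' deposited table. Of 12 seed storage genes, markers of embryo tissue, 6 were lower and 0 higher (BH p = 0.0462), with SESA2 at -3.69, SESA3 at -2.86, EM6 at -2.84 and OLEO2 at -2.72 in the authors' deposited table. Only 1 of 20 antenna genes was called (LHCA5 at -0.67 in the authors' deposited table, BH p = 0.553), and of 17 chlorophyll genes 2 (PORB at 0.85 and FLU at 0.61, BH p = 1.00). PHYB, the main red light receptor, was at -0.67, FHL at 1.07, PIF5 at 0.69 (AT3G59060.4) and PIF7 at 0.67 in the authors' deposited table. Among splicing factors, 3 were higher and 7 lower (BH p = 0.0924), with U2AF65A at -1.72, U1-70K at -1.07, GRP8 at -0.88 and PTB3 at 1.68 in the authors' deposited table, and among SR proteins SCL30 was at -0.73 and RS31 at 0.73 (4 of 20 called, BH p = 1.00). LNK2 (-1.16), RVE8 (-1.03), CCA1 (-1.01) and ZTL (-0.90) were among 8 of 24 clock genes called in the authors' deposited table (BH p = 0.210).

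In total 2287 transcripts were higher and 2851 lower in swap1 in red light. Beside PR1 the lowest were CYP71A12 (-5.36), AT1G14950 (-5.27), AT2G34315 (-5.07) and AT5G35660 (-4.68), and the highest were AT3G42100 (7.99), ATCG01280 (7.79, SE 2.11), AT5G27845 (5.19), AT3G02360 (4.46) and WAK3 (4.45) in the authors' deposited table. Auxin genes (7 of 25 called; IAA19 at -1.53, IAA7 at 1.19), flavonoid genes (6 of 18; MYB12 at -1.48, DFR at -1.09), ABA genes (2 of 14; RAB18 at -2.81) and heat shock genes (3 of 10; HSP17.4 at -1.03), with values from the authors' deposited table, did not pass (lowest BH p = 0.343). Photoreceptors (2 of 20), negative regulators (2 of 13), mutated genes (1 of 3) and root hair markers (3 of 8, all higher, with PRP3 at 1.11 in the authors' deposited table) did not pass either (lowest BH p = 0.406). No GO term with at least 10 genes passed in the authors' deposited table (lowest adjusted p-value 0.225, for defense response among others). The swap1 effect was shared between dark and red light: 780 loci were higher in both (106.8 expected) and 1121 lower in both (187.0 expected). Of 2170 transcripts called in both, 96.6% had the same direction and 273 differed, among them CHS (-2.39 dark, -0.64 red in the authors' deposited table). At an absolute log2 fold change of at least 1, 2565 transcripts were counted, and 141 transcripts differed between lights by at least 1.

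Most introns called between red light and dark in WT had lower retention in red light. Of 1390 introns called between red light and dark, 378 had higher retention in red light and 1012 lower, so 27.2% were higher (95% interval 24.9 to 29.6). The authors called 2007 regions in 1458 loci. Clock genes held called regions in 6 of 24 loci (BH p = 0.00907), and in the authors' deposited table the LHY introns 5 (chromosome 1, 36000 to 36089) and 7 (35475 to 35566) changed by -2.30 and -2.21. HFR1 intron 4 (chromosome 1, 466248 to 466731) changed by -0.83, PIF7 intron 5 (chromosome 5, 24638996 to 24639080) by -1.63 and PTB3 intron 1 (chromosome 1, 16278194 to 16278454) by -0.65 in the authors' deposited table. The regions of lowest FDR lay in PYK10, a beta-glucosidase (chromosome 3, 2843117 to 2843569, inclusion change 0.899), BOU (chromosome 5, 18989812 to 18990316, 0.838), PHOT1, the blue light receptor (chromosome 3, 16816915 to 16818544, 0.581), AT5G64130 (exon 2, chromosome 5, 25665164 to 25665259, 0.907) and DI19 (chromosome 1, 21074172 to 21074677, 0.767) in the authors' deposited table. Carbohydrate metabolism (44 genes, 0.00697) and circadian rhythm (19 genes, 0.0205) had the lowest adjusted p-values among GO terms in the authors' deposited table. No other list passed (Fisher's exact test, lowest BH p = 0.162). Small nucleolar RNAs (snoRNAs), which are kept in the nucleus, had 20 of 24 called members lower in red light (exact binomial test, BH p = 0.00441). This and the other snoRNA tests were chosen after the data were seen. With an inclusion change of at least 0.2, 423 regions were counted, and the clock list did not pass against only loci with called splicing (Fisher's exact test, BH p = 0.226).

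In swap1 most called introns had higher retention in red light, unlike in WT. Of 2232 introns called, 1548 had higher retention in red light and 684 lower, or 69.4% higher (67.4 to 71.3), against 27.2% in WT (Fisher's exact test, BH p = 1.06e-137). This direction depended on the kind of evidence, since among introns with a junction inclusion change of at least 0.2 the share was 37.9% (exact binomial p = 0.0869). The authors called 3098 regions in 2089 loci, and 582 had that inclusion change. PTB3 intron 1, lower in WT, rose by 0.77 in swap1, and RS40 intron 2 (chromosome 4, 13024832 to 13025162) rose by 0.95, BRR2A intron 4 (chromosome 1, 7302052 to 7302578) by 0.78, PIF5 intron 1 (chromosome 3, 21829914 to 21830181) by 0.76 and RRC1 intron 6 (chromosome 5, 8638561 to 8638651) by 0.78 in the authors' deposited table. Other introns still fell, among them LHY intron 5 (-2.33), PIF7 intron 5 (-1.88) and BBX25 intron 2 (chromosome 2, 13382972 to 13383062, -1.53) in the authors' deposited table. The lowest FDR belonged to RBCS1A, a small subunit of Rubisco (inclusion change 0.633), CAT3 (exon 2, chromosome 1, 7145605 to 7145712, 0.581), ARFA1E (chromosome 3, 23053456 to 23053546, 0.903), AT5G57770 (intron 7, chromosome 5, 23401330 to 23401425, 0.658) and PHOT1 (chromosome 3, 16816915 to 16818544, 0.617) in the authors' deposited table. Of 508 bins called by light in both genotypes, 65.7% moved in the same direction. No list passed (clock 3 of 24 loci, BH p = 0.814), and no GO term with at least 10 genes did (lowest adjusted p-value 0.215 in the authors' deposited table). In swap1, 18 of 20 called snoRNAs were higher in red light (exact binomial test, BH p = 0.00161).

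**Figure D3:**
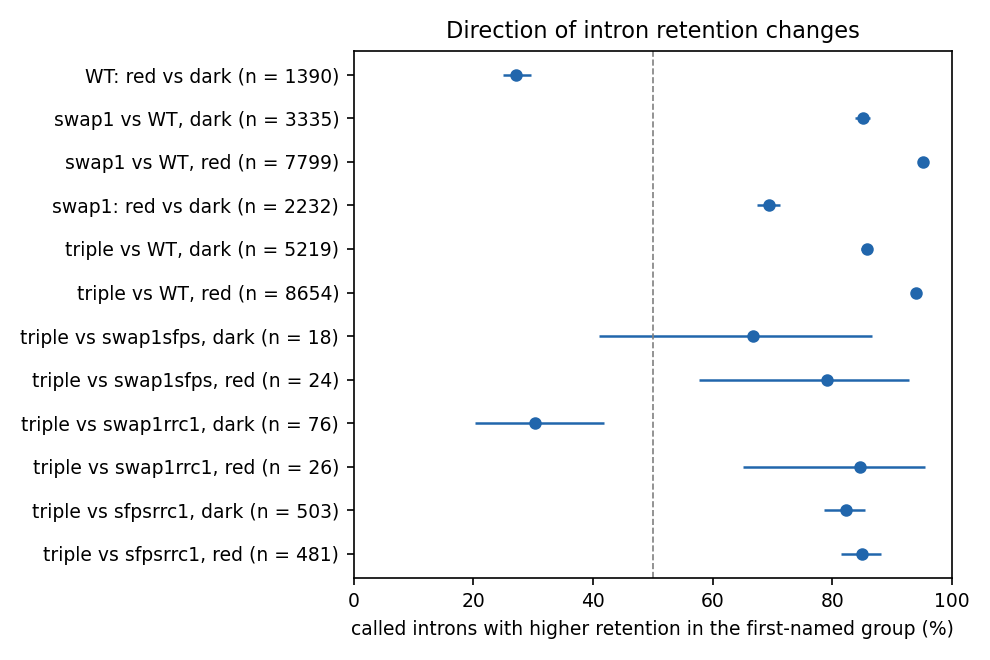
Percent of called introns with higher retention in the first-named group for 12 comparisons (points), with exact 95% intervals, the number of introns and a dashed line at 50%. WT between lights lies at 27.2% and swap1 between lights at 69.4%, and the comparisons of swap1 or the triple mutant with WT lie between 85.2% and 95.2%.

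Most introns called between swap1 and WT had higher retention in swap1. In the dark 2840 of 3335 called introns had higher retention in swap1 than in WT (85.2%, 83.9 to 86.3), and in red light 7426 of 7799 (95.2%, 94.7 to 95.7), a difference between lights past the threshold (Fisher's exact test, BH p = 1.98e-66). The authors called 7770 regions in 3957 loci in the dark and 12488 in 6123 loci in red light. Called pseudogenes were also mostly higher in swap1, 127 of 183 in the dark and 122 of 187 in red light. Genomic DNA in the swap1 libraries was not tested as a cause of the retention in these 2 comparisons. TOC1 intron 1 (chromosome 5, 24675673 to 24675989) rose by 1.08 in the dark and 1.16 in red light, and RS41 intron 1 (chromosome 5, 21130434 to 21131075) by 1.23 and 1.52 in the authors' deposited table. COP1 intron 6 (chromosome 2, 13980525 to 13981051) rose by 0.68 in the dark in the authors' deposited table. In red light COP1 intron 7 (13981131 to 13981420) rose by 0.81, HFR1 intron 4 by 0.85, FHY1 intron 1 (chromosome 2, 15802323 to 15802643) by 0.80, PIF3 intron 2 (chromosome 1, 3076809 to 3077172) by 0.64, XCT intron 4 (chromosome 2, 9066252 to 9066711) by 1.19 and MAC3B intron 4 (chromosome 2, 14130001 to 14130338) by 1.32 in the authors' deposited table. Introns also fell, such as U2AF65A intron 11 (chromosome 4, 17294604 to 17294703, -1.21) and RRC1 intron 2 (chromosome 5, 8639488 to 8639662, -1.14) in the dark in the authors' deposited table.

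SR proteins, which guide splice site choice, held called regions in 17 of 20 loci in red light (Fisher's exact test, BH p = 2.86e-07) and 7 of 20 in the dark (BH p = 0.0898). Other splicing factors did so in 15 of 28 (Fisher's exact test, BH p = 0.00258) and 8 of 28 (BH p = 0.216), and clock genes in 13 of 24 (BH p = 0.00492) and 11 of 24 (BH p = 0.00216). No other list passed in either light (Fisher's exact test, lowest BH p = 0.0690, the antenna list with 0 of 20 loci called in red light). Unannotated junctions changed in RS41 (chromosome 5, 21130433 to 21130627, inclusion change 0.818 dark, 0.793 red), RS40 (exon 2, chromosome 4, 13025273 to 13025358, 0.755, 0.721), TOC1 (chromosome 5, 24675672 to 24675761, 0.813, 0.786) and COP1 (chromosome 2, 13980524 to 13980643, 0.538, 0.459) in the authors' deposited table. The regions of lowest FDR lay in AT2G35880 (chromosome 2, 15065347 to 15065836, 0.560 dark and chromosome 2, 15065269 to 15065836, 0.565 red) and ACR12 (chromosome 5, 1369700 to 1370075, 0.661, 0.594) in both lights in the authors' deposited table. They also lay in CAT3 (exon 5, chromosome 1, 7145780 to 7145896, 0.795), IAA7 (exon 5, chromosome 3, 8196762 to 8196852, 0.401) and VHA-C3 (chromosome 4, 18147405 to 18148098, 0.310) in the dark in the authors' deposited table. In red light they lay in PYK10 (chromosome 3, 2843117 to 2843569, 0.810), AT1G15740 (chromosome 1, 5411053 to 5411493, 0.742) and APX1 (chromosome 1, 2437555 to 2438000, 0.469) in the authors' deposited table. Of the 1512 bins called in both lights, 95.5% moved the same way, and 3860 regions were shared. DNA repair (62 genes, 1.54e-05) led the GO terms in the dark, and chromatin organization (81 genes, 1.13e-05) and RNA splicing (54 genes, 4.77e-05) in red light in the authors' deposited table. snoRNAs were lower in 12 of 13 called cases in the dark (exact binomial test, BH p = 0.00854) and higher in 26 of 28 in red light (BH p = 3.03e-05). Among introns with an inclusion change of at least 0.2, 56.4% were higher in the dark (exact binomial p = 0.419). No list passed against only loci with called splicing (Fisher's exact test, lowest BH p = 0.0901, SR proteins in red light).

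The triple mutant had the same widespread intron retention. Against WT, 4478 of 5219 introns were higher in the dark (85.8%, 84.8 to 86.7) and 8143 of 8654 in red light (94.1%, 93.6 to 94.6), again a difference between lights (Fisher's exact test, BH p = 1.18e-58). The authors called 11390 regions in 5235 loci in the dark and 14869 in 6683 in red light. RS41 intron 1 was at 1.06 in the dark and 1.24 in red light, FHY1 intron 1 at 0.63 and 0.91, and TOC1 intron 1 at 1.07 in the dark in the authors' deposited table. COP1 intron 6 was at 0.78 in the dark, HFR1 intron 4 at 0.94 and MAC3B intron 4 at 1.53 in red light, and U2AF65A intron 11 at -1.43 in the dark in the authors' deposited table. SR proteins held called regions in 14 of 20 loci in the dark (Fisher's exact test, BH p = 2.24e-05) and 13 in red light (BH p = 0.00148), other splicing factors in 14 of 28 (BH p = 0.00214) and 17 (BH p = 6.08e-04), and clock genes in 11 of 24 (BH p = 0.0150) and 13 (BH p = 0.0102). The lowest FDR belonged to AT2G35880 (chromosome 2, 15065347 to 15065836, 0.564 and chromosome 2, 15065269 to 15065836, 0.568) and AT1G15740 (chromosome 1, 5411053 to 5411493, 0.708, 0.712) in both lights in the authors' deposited table. The next belonged to CAT3 (exon 6, chromosome 1, 7145923 to 7145957, 0.851), AT2G37130 (exon 1, chromosome 2, 15599786 to 15599929, 0.634) and SPPL2 (chromosome 1, 23618636 to 23619006, 0.541) in the dark in the authors' deposited table. In red light it also belonged to PYK10 (chromosome 3, 2841881 to 2841988, 0.796), RBCS1B (chromosome 5, 15384589 to 15384985, 0.747) and RBCS1A (chromosome 1, 25048701 to 25049079, 0.647) in the authors' deposited table. DNA repair (74 genes, 9.88e-06) and chromatin organization (83 genes, 2.36e-05) led the GO terms in dark and red light in the authors' deposited table. The comparisons of swap1 and of the triple mutant share the WT libraries. They had 2017 intron bins in common in the dark and 4910 in red light, where a simulation with the shared controls gave 644.6 and 1664 and independence 132.7 and 514.6. Both expectations used all 131151 annotated introns of the protein-coding nuclear genes, whether or not they could be tested. That background is too wide and makes the expected numbers too low. No other list passed (Fisher's exact test, lowest BH p = 0.308), and none did against only loci with called splicing (lowest BH p = 0.289).

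Adding swap1 to sfpsrrc1 changed far more regions than adding either other mutation. The triple mutant differed from sfpsrrc1 in 2181 regions (1506 loci) in the dark and 1690 (1242 loci) in red light, with 82.3% (78.7 to 85.5) and 85.0% (81.5 to 88.1) of introns higher in the triple mutant, which were not shown to differ (Fisher's exact test, BH p = 0.316). These changes were like those of swap1 against WT, a comparison with no shared library: 48.9% of the regions in the dark and 40.9% in red light were shared, and 97.4% and 95.7% of shared bins had the same direction. SR proteins held called regions in 7 of 20 loci in the dark (Fisher's exact test, BH p = 8.20e-04) and 2 in red light (BH p = 0.542). The lowest FDR in the dark belonged to PPDK (chromosome 4, 8866954 to 8867310, junction changes 0.346 and chromosome 4, 8867101 to 8867229, 0.718) and UBL5 (chromosome 5, 16912935 to 16913611, 0.627) in the authors' deposited table. Red light gave RBCS1A (chromosome 1, 25048701 to 25049079, 0.647), MLP28 (chromosome 1, 26710615 to 26711200, 0.435) and PRPS20 (chromosome 3, 5116405 to 5116521, 0.823) in the authors' deposited table. Chromatin organization led the GO terms in the dark (35 genes, 7.08e-06), and none with at least 10 genes passed in red light (lowest 0.0855) in the authors' deposited table. With an inclusion change of at least 0.2, 57.1% of introns were higher in the dark (exact binomial p = 1.00) and 60.0% in red light (exact binomial p = 0.754).

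Adding rrc1 to swap1sfps changed 188 regions in the dark and 223 in red light, and adding sfps to swap1rrc1 changed 288 and 215. With rrc1 added, 66.7% (41.0 to 86.7) of 18 introns were higher in the dark and 79.2% (57.8 to 92.9) of 24 in red light, which were not shown to differ (Fisher's exact test, BH p = 0.483). With sfps added, 30.3% (20.2 to 41.9) of 76 introns were higher in the dark and 84.6% (65.1 to 95.6) of 26 in red light (Fisher's exact test, BH p = 2.62e-06). The lowest FDR with rrc1 added belonged to ATMS1 (chromosome 5, 5935203 to 5935762, 0.855), ALDH7B4 (chromosome 1, 20198068 to 20198162, 0.467) and an exon 1 bin of PWP2 (chromosome 1, 5308219 to 5308843, log2 1.73) in the dark in the authors' deposited table. In red light it belonged to LTPG1 (chromosome 1, 9741083 to 9741780, 0.332), AT2G33830 (chromosome 2, 14310077 to 14310196, 0.337) and NAI2 (chromosome 3, 5400558 to 5401543, 0.624) in the authors' deposited table. With sfps added it belonged to PIP3 (chromosome 4, 16709749 to 16709839, 0.634), PIP2A (chromosome 3, 19804256 to 19804390, 0.675), both aquaporins, and ALA3 (exon 27, chromosome 1, 22020083 to 22020106, 0.912) in the dark in the authors' deposited table. In red light it belonged to PYK10 (chromosome 3, 2843147 to 2843604, 0.583), exon 2 of ILA (chromosome 1, 24082539 to 24082720, log2 3.24) and exon 3 of RDR1 (chromosome 1, 5095210 to 5095360, log2 -3.56) in the authors' deposited table. The mutated genes were called in 2 of 3 loci with sfps added in the dark (Fisher's exact test, BH p = 0.00241) and with swap1 added in the dark (BH p = 0.0484) and red light (BH p = 0.0352). These p-values are no sign of a shared function, since with swap1 added SWAP1 is the mutated gene itself. With sfps added SFPS was not called, and the called loci were SWAP1 and RRC1, which are mutant in both groups. No other list passed in the comparisons of doubles with the triple mutant except SR proteins with swap1 added. Against only loci with called splicing the mutated genes with sfps added in the dark alone passed (Fisher's exact test, BH p = 0.0349). The same double shared few regions between dark and red light, 3.72% of the shorter list with rrc1 added and 8.37% with sfps added, against 38.9% with swap1 added. In the authors' deposited table, no GO term with at least 10 genes passed for swap1rrc1 in the dark or swap1sfps in red light (lowest adjusted p-value 0.134), and the other light condition of each had no term of that size. With an inclusion change of at least 0.2 the introns with sfps added were 0% higher in the dark (exact binomial p = 1.00), and with rrc1 added 100% in red light (exact binomial p = 0.5). These shares rest on at most 1 and 2 introns and show no contrast.

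Introns with higher retention in swap1 in red light were long. Their median over 4547 loci was 232.0 bases against 103.0 for the other introns of the same loci, and they were longer in 77.1% of loci (75.9 to 78.3). Introns with lower retention had medians of 99.5 and 102.0 bases in 330 loci and were longer in 46.5% (40.9 to 52.0). In the dark, introns higher in swap1 had a median of 126.0 against 103.5 bases and those lower 129.0 against 106.5. With light, introns that fell in WT (275.0 against 103.5 bases) and those that rose in swap1 (276.0 against 105.0) were long.

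**Figure D4:**
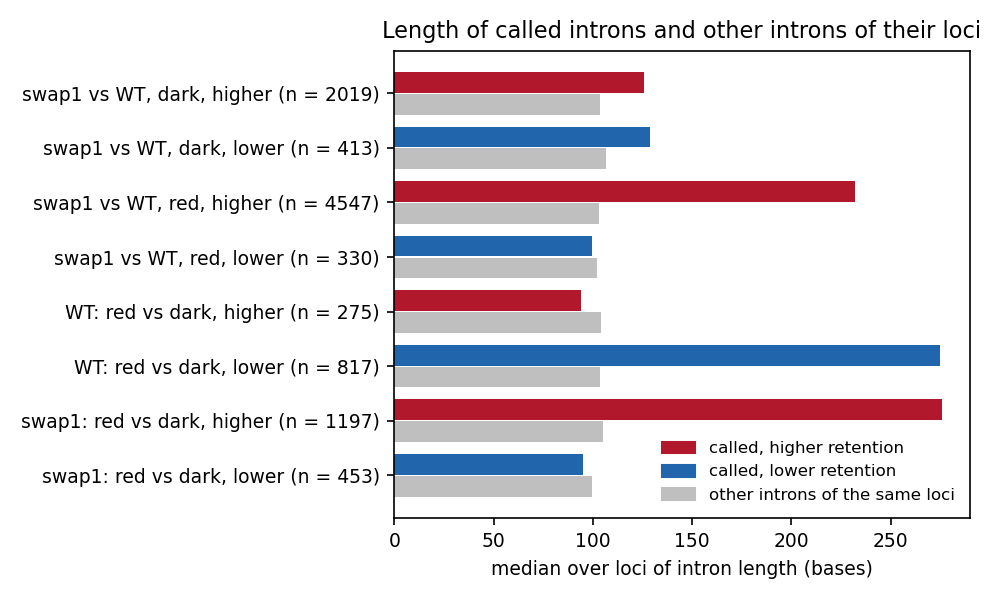
Median over loci of the length in bases of called introns with higher (red) or lower (blue) retention and of the other introns of the same loci (grey), with the number of loci. Introns higher in swap1 in red light (232.0 against 103.0 bases) and introns lower in red light in WT (275.0 against 103.5 bases) stand out as long.

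Loci with changed splicing overlapped loci with changed expression. For light in WT 580 loci were shared (295.0 expected, odds ratio 2.81, Fisher's exact test, BH p = 1.46e-69) and in swap1 912 (509.8 expected, odds ratio 2.63, BH p = 1.10e-89). For swap1 against WT, 620 were shared in the dark (497.2 expected, odds ratio 1.36, Fisher's exact test, BH p = 3.22e-10) and 1306 in red light (1007 expected, odds ratio 1.53, BH p = 2.88e-30). Where introns were higher in swap1 in red light and the locus was called in expression, 476 loci were higher and 476 lower. Highly expressed genes can be called more easily in both kinds of table, and the tables hold only called genes. Expression was also called per transcript, so a change between isoforms can enter both kinds of table and raise the overlap. Loci with several isoforms were called more often in expression in each comparison, such as 20.9% against 15.7% of single-isoform loci for swap1 in red light. How much of the overlap comes from this was not tested.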

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

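In this part the tests on WT red-light libraries, pseudogenes, snoRNAs and shared regions of the doubles were chosen only after the result was seen. A result stands here because the change between light conditions, or between genotypes, differed by a test of the difference itself.

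The light response differed between swap1 and WT in 1233 transcripts. As log2 differences of swap1 minus WT, genes of the antenna and chlorophyll lists had LHCB1.4 at 5.21, LHCB1.1 at 3.96, LHCB1.2 at 1.80, LHCA1 at 0.76, LHCB2.2 at 0.56, CRD1 at 0.75, GUN5 at 0.69, GUN4 at 0.68, HEMA1 at 0.47, PORB at 1.41 and PORA at 0.71. Among regulators were HYH (1.60), BBX25 (0.91), SPA1 (0.60), FHL (0.55), SPA3 (0.35), PIF5 (1.38, transcript AT3G59060.3), PIF4 (-1.08) and PIF7 (-0.99), and among clock genes LHY (1.08), LNK1 (-0.55) and BOA (-0.98). Another PIF5 transcript, AT3G59060.4, was at -0.19 (SE 0.45) and is not among the 1233. The PIF5 value therefore holds for AT3G59060.3 and not for the gene as a whole. Auxin, flavonoid and splicing lists had SAUR23 (-1.12), SAUR22 (-0.97), ATHB2 (-0.34), 4CL3 (2.43) and GRP7 (-0.45). Stress lists had HSP21 (2.52), HSP17.6II (1.64), HSP70-4 (-0.51), RD29B (-2.27) and RD29A (-1.61). Among the genes of largest change were THI2.2 (2.79, SE 1.05), CYP78A10 (-6.02, SE 1.32), AT5G57760 (-1.39, SE 0.41) and AT5G24080 (-7.68, SE 1.56). With such SE the sizes of these differences are imprecise. No explanation of these differences was tested. In swap1 against WT, 9 of 20 antenna genes were lower in the dark, and 1 of 20 was called in red light, also lower. Chlorophyll genes had 6 of 17 lower and 1 higher in the dark, and 0 lower and 2 higher in red light. The larger antenna fold changes thus went with lower dark levels for some genes, and with no called higher level in red light. The near-identical LHCB1 copies may share reads, which was not checked.

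The effect of swap1 differed between red light and dark in 273 transcripts. This is in effect the same difference as that of the light responses above, so it is no separate result. It was taken over the 2170 transcripts called in both comparisons of genotypes, instead of the 4679 called in both comparisons of light. As log2 differences of red light minus dark, MYB11 was at 4.05, AT4G04750 at 2.84, HSP21 at 2.52, CHS at 1.75 and SKIP at -0.45.

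Among introns called between red light and dark 27.2% had higher retention in red light in WT and 69.4% in swap1, but 65.7% of the 508 bins called in both genotypes moved the same way. With an inclusion change of at least 0.2 the shares were 24.3% in WT and 37.9% in swap1. At most 37 introns in WT and 60 in swap1 were left there. The swap1 share was then not shown to differ from 50% (exact binomial p = 0.0869). The WT red-light libraries take no part in the comparison that gave 69.4% (67.4 to 71.3), so their standing apart is no explanation of it, which follows from the design and not from a separate test. For the 27.2% in WT they stay open, since the triple mutant also exceeded WT more in red light (94.1%) than in the dark (85.8%), and swap1 did too (95.2% against 85.2%). For genomic DNA in the swap1 red-light libraries the tests point opposite ways. Loci with introns higher had 0.344 times the base mean of loci with introns lower (0.242 to 0.541), as genomic DNA predicts. This ratio covers only loci also called in expression, 464 of 1210 with introns higher and 242 of 439 with introns lower. Against genomic DNA, 35% of called pseudogenes were higher (27.1 to 43.5). Pseudogenes were also mostly lower in red light in WT (36.6% higher), so genomic DNA stays open. A larger share of unspliced nuclear RNA could account for the share in swap1, where 90.0% of called snoRNAs were higher (68.3 to 98.8). snoRNAs went with introns in WT between lights (16.7% higher) and in swap1 against WT in red light (92.9%). In swap1 against WT in the dark they did not, with 7.69% of called snoRNAs but 85.2% of introns higher. The snoRNA value therefore cannot decide. In swap1 11.1% of loci with several called introns went both ways (where 52.3% were expected), as more unspliced nuclear RNA predicts. WT gave nearly the same, 12.7% (49.1% expected), although most of its introns fell. Introns of a locus thus moved together in either genotype, and this value cannot decide. A splicing defect in light, more transcription and differences in extraction would each give such RNA, and no value here separates them.

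Adding sfps to swap1rrc1 gave fewer retained introns in the dark (30.3% higher) and more in red light (84.6%). The doubles with swap1 shared 18.1% of regions with each other in the dark, against 3.72% for swap1sfps and 8.37% for swap1rrc1 between dark and red light. Chance differences of the triple mutant libraries, which both doubles are compared with, could therefore account for many of these regions, although this test was shaped by values already seen. Splicing changes that depend on light would also give low shares between dark and red light, so they stay open, and no value separates the explanations. Loci shared by both doubles were 36 in the dark, and simulated shared controls gave fewer (17.9), though a simulated bound excludes nothing. The draws used all 22241 genes with an annotated intron, a background that is too wide and makes the simulated number too low.

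Introns with higher retention in swap1 in red light were longer than the other introns of their genes. If longer introns only gave more power, introns with lower retention would be longer as well, and they were longer in 46.5% of loci (40.9 to 52.0). In the dark introns lower in swap1 were longer in 61.7% of loci (56.8 to 66.4) and those higher in 59.9%, as power predicts. With light, introns that rose in WT were longer in 34.4% (28.8 to 40.4) and those that fell in swap1 in 47.2% (42.5 to 51.9). The red-light interval for swap1 against WT includes 50% and the dark goes with power. Greater power on long introns may not be the whole explanation in red light but stays open. No biological explanation was tested for the length.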

How the results depend on the processing

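Chosen only after the result was seen were the background of called genes for the gene lists, the background of genes with introns, the common bin FDR and expression counted by locus. Of 173 alternatives over 55 results, 117 kept the result, 50 moved it, 5 made it weaker and 1 reversed it. No alternative changed the direction or the side of the threshold for the overlap of expression comparisons with each other or with splicing. An FDR of at most 0.01 kept 38 results, 1 region per locus 12, a bin FDR of at most 0.03 kept 12 and a threshold of 0.01 kept 10. A count was taken as kept unless it changed by a factor of more than 1.5, so kept counts can still differ in size. The tables with the triple mutant were already cut at a bin FDR of 0.03. That setting therefore tested only the tables of WT and swap1. No paired analysis was possible because the tables hold results of groups and no value for a single library. For the same reason a replicate block, a new test on counts by edgeR, a filter on low counts, leaving out single libraries and other splits of the libraries were not run, and limits from depth are unknown.

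Larger minimum changes lower counts by construction. At an absolute log2 fold change of at least 1 the counts were 3525 (light in WT), 4299 (light in swap1), 1969 (swap1 in the dark) and 2565 (swap1 in red light). At an absolute difference of at least 1, 353 transcripts differed in light response and 141 in swap1 effect, and at a threshold of 0.01, 799 differed in light response. An inclusion change of at least 0.2 in effect keeps regions with junction evidence: 423 for light in WT, 582 for light in swap1, 4085 and 3938 for swap1 in dark and red light, 5717 and 5426 for the triple mutant and 185 for sfps added in the dark. With both bin and junction support 37, 60, 75, 100, 151 and 150 regions were left in these first 6 comparisons, 2 with rrc1 added in red light, 1 with sfps added in the dark, and 7 and 11 with swap1 added. The other comparisons with rrc1 or sfps added had no region with such support and give no value. Counted by distinct loci, swap1 changed 3957 (dark) and 6123 (red) and the triple mutant 5235 and 6683.

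Intron retention depended on the kind of evidence. With an inclusion change of at least 0.2 the share of introns higher in red light in swap1 reversed from 69.4% to 37.9%. The shares were 56.4% for swap1 in the dark, 57.1% and 60.0% with swap1 added, 100% with rrc1 added in red light and 0% with sfps added in the dark, none of them past the threshold, with few introns left. At most 2 introns were left with rrc1 added in red light and 1 with sfps added in the dark. With rrc1 added in the dark or sfps added in red light no intron was left. The cause was not tested for these shares.

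Shared regions depended on how sharing is defined, and a looser definition raises them by construction. By the same locus the percentages were 73.6 (swap1 in dark and red light), 40.6 (light in both genotypes), 67.2 and 72.9 (swap1 added and swap1, dark and red), 79.5 and 79.6 (swap1 and triple mutant), 8.75 (rrc1 added in dark and red) and 48.9 (swap1 added in dark and red). By at least 1 base they were 61.8, 31.4, 57.7 and 53.0, 74.8 and 71.1, and 45.0, leaving out rrc1. At an FDR of at most 0.01 they were 53.7, 30.7, 74.6 and 70.4 (swap1 and triple mutant) and 41.7 (swap1 added), and the cause was not tested.

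Gene lists depended on the background. Against genes called in at least 1 table, 3 instead of 24 results of lists passed in expression and 1 instead of 15 in splicing. The cause was not tested. The 3 are the antenna list under light in both genotypes and, called less often than other genes, in swap1 in red light. All 20 antenna genes enter that background because light called them, so the last of these is partly set by the choice of background.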

Other observations

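All tests of transcript groups in this part were chosen only after the tables were seen. Transcripts of the chloroplast genome were lower in swap1 than in WT in the dark (1 of 21 called higher, exact binomial test, BH p = 4.50e-05) and higher in red light (18 of 22, exact binomial test, BH p = 0.00592). In swap1 light raised them (34 of 35, exact binomial test, BH p = 6.29e-09), while in WT 9 of 26 were higher (exact binomial test, BH p = 0.180). Mitochondrial transcripts were lower in red light in swap1 (1 of 13 called higher, exact binomial test, BH p = 0.00513) and lower in swap1 than in WT in red light (2 of 20 higher, exact binomial test, BH p = 7.55e-04), with 0 called between the genotypes in the dark.

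Transfer RNAs were higher in swap1 in the dark (19 of 21, exact binomial test, BH p = 0.00111) but had 9 of 18 higher in red light. MicroRNA precursors were lower in swap1 in the dark (2 of 13 higher, exact binomial test, BH p = 0.0449). Pseudogene transcripts were mostly higher in swap1 than in WT, 127 of 183 in the dark (exact binomial test, BH p = 3.23e-06) and 122 of 187 in red light (exact binomial test, BH p = 2.47e-04). With light they were mostly lower, 30 of 82 higher in WT (exact binomial test, BH p = 0.0441) and 49 of 140 in swap1 (exact binomial test, BH p = 0.00162). No group of long noncoding RNAs passed (lowest exact binomial test BH p = 0.317). These tests count transcripts, which are not independent of each other.

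Transcripts of high base mean (1000 or more) were mostly lower in swap1 than in WT, with 233 of 785 higher in the dark (exact binomial test, BH p = 5.62e-30) and 248 of 1131 in red light (exact binomial test, BH p = 9.35e-83). Those of low base mean (below 10) were mostly higher, 143 of 209 in the dark (exact binomial test, BH p = 2.66e-07) and 130 of 216 in red light (exact binomial test, BH p = 0.00513).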
